A study of Mus musculus with 10 samples.

How the data were processed

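RNA-seq counts were analysed from tumour epithelium of KPFSR mice, a genetically engineered model of pancreatic ductal adenocarcinoma. Per the labels, 4 samples came from animals given corn oil, the vehicle, and 6 from animals given tamoxifen. The epithelium was collected from frozen sections by laser capture microdissection. Per the labels' protocols, RNA was purified with a Qiagen micro kit, amplified as cDNA with the SMART-seq v4 low-input kit and made into libraries with Nextera XT. These kits do not mark strand. The labels do not tie samples to animals, so p-values measure the spread between these samples, and they are too small if samples of a group share an animal.

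The authors deposited raw read counts per gene symbol in 1 table. Per the submitters' processing notes, bcl2fastq 2.17, STAR 2.5.2b and featureCounts 1.5.0-p3 were used with the mm10 build. The gene annotation, the strand setting, the handling of reads that map to several places and the rule that chose the listed genes are not given in the sources used here. The table lists 15624 genes, of which 3 have no count in any library. It lists none of the mitochondrially encoded genes, so the planned mitochondrial share was not analysed here. Gene positions were taken from GENCODE M21 on GRCm38, the assembly behind mm10, in which 14649 symbols (93.8%) were found.

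Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. Genes with enough counts by filterByExpr (13006 genes) were scaled with TMM factors and tested for tamoxifen against corn oil by the quasi-likelihood F test without covariates, with Benjamini-Hochberg adjustment at an FDR of 0.05. Levels are TMM-scaled CPM (normalised CPM) with SD. Log2 CPM used a prior count of 2. The F test gives no standard error, so the SE of a log2 fold change is its absolute value divided by the square root of F. Slc7a11 and library measures were also tested by an exact two-sided permutation test over the 210 arrangements of 4 and 6 libraries, whose smallest p is 0.00952. Of 34 gene lists, the 28 with at least 5 tested genes were compared with all other genes by camera from limma 3.58.1 with a preset inter-gene correlation of 0.01. Camera was repeated with an estimated correlation, and fry and an exact permutation of list means were alternatives.

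The gene lists, the rule for named genes and the alternatives not said to be added later were fixed before the data were examined. The rule was as follows. Slc7a11 was always named. Genes past the FDR with a mean log2 CPM of at least 3 were named up to 10 per direction. Where a direction held fewer than 8, genes of smallest unadjusted p under 0.05 filled it and are said not to pass. Of each list described, up to 4 members past the FDR were named, and otherwise the 2 of smallest p with a mean log2 CPM of at least 0. Of lists for other cell types, the 2 most abundant members were also named.

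The alternatives were RLE and upper-quartile factors, no filter, a filter of 5 CPM in 4 libraries, limma voom with sample quality weights, DESeq2 1.42.0, edgeR with robust dispersion, an FDR of 0.1, covariates for detected genes, sex and fibroblast marker level, and leaving out each library. Counting tamoxifen replicates 1 to 3 as 1 sample, leaving these 3 out, leaving out tamoxifen replicates 4 and 6, and counting genes at equal depth were added after seeing the data. Sex was read from Xist and Ddx3y, which gave 2 female and 2 male corn oil libraries and 1 female and 5 male tamoxifen libraries.

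The gene test was tested on simulated data for tamoxifen against corn oil, with 12649 genes in the step and 50 genes changed at each fold. It recovered 4% of genes changed 2-fold, 38% at 4-fold, 44% at 8-fold and 78% at 16-fold, with 3 false calls, so most changes of the lower sizes would be missed. On simulated data with independent genes, 3 of 200 unchanged lists had a camera p under 0.05. Figures were drawn with matplotlib 3.10.9.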

Results

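Gene expression was measured in laser-captured tumour epithelium from KPFSR pancreatic tumours of mice given corn oil (n = 4) or tamoxifen (n = 6). Total counts per library ran from 16473900 to 36132300 with corn oil and from 6899350 (replicate 6) to 19462100 with tamoxifen. Corn oil libraries held 25718200 ± 8053880 counts (SD, n = 4) and tamoxifen libraries 15080900 ± 5145910 (SD, n = 6), an exact permutation p of 0.0476 that became 0.0714 after adjustment over 3 library measures. The 10 most abundant genes took 11.5% ± 0.866 (SD, n = 4) of counts with corn oil and 8.74% ± 1.95 (SD, n = 6) with tamoxifen, with an exact permutation p of 0.0381 and an adjusted p of 0.0714. Genes with a count numbered 13690 ± 284 (SD, n = 4) and 13460 ± 1123 (SD, n = 6), with an exact permutation p of 0.752. Counted at equal depth they numbered 13312 ± 349 (SD, n = 4) and 13148 ± 977 (SD, n = 6), with an exact permutation p of 0.771.

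Tamoxifen replicates 1 to 3 resembled each other more than any other libraries did. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.921 to 0.963 among these 3 and at most 0.878 for any other pair. Their counts still differed beyond sampling noise, with a mean chi-square per gene of at least 25.04, so they are not copies of 1 library and each was kept. That value does not show that the 3 are independent samples. The labels do not say whether they share an animal. Results are therefore also given with these 3 counted as 1 sample, an alternative chosen after seeing the data.

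**Figure D1:**
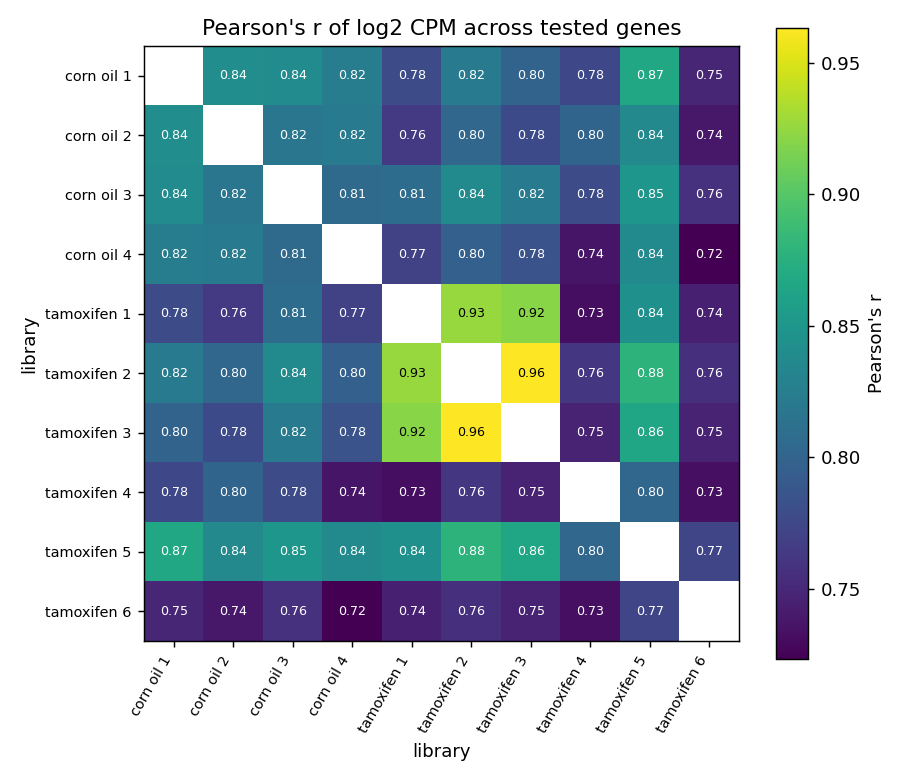
Pearson's r of log2 CPM across the 13006 tested genes for each pair of the 10 libraries, with colour and printed value giving r. The 3 pairs among tamoxifen replicates 1 to 3 lie at 0.921 to 0.963, above all other pairs.

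The first question was whether the targeted gene differed. Knowledge of the model, not the labels, makes Slc7a11 the gene that tamoxifen deletes. Slc7a11, the cystine-importing subunit of the cystine/glutamate exchanger, was lower in each of the 6 tamoxifen libraries than in any corn oil library. It stood at 32.1 ± 8.65 normalised CPM (SD, n = 4) with corn oil and 12.1 ± 5.79 (SD, n = 6) with tamoxifen, a log2 fold change of -1.41 (SE 0.44). The exact permutation p was 0.00952, the smallest that 4 and 6 libraries can give, while the edgeR p adjusted over all genes was 0.311. Corn oil libraries held 559 to 995 reads of the gene and the shallower tamoxifen libraries 80 to 372, before scaling for depth. The gap in normalised CPM was narrow, with tamoxifen replicates 4 and 5 at 19.3 and 18.5 and corn oil replicate 4 at 23.2. Slc7a11 lies on chromosome 3 at 49892526 to 50443614 on the minus strand of GRCm38, and its gene total may include exons outside the deleted part. With tamoxifen replicates 1 to 3 counted as 1 sample the log2 fold change was -1.13 and the exact permutation p 0.0286, the smallest possible. Without these 3 libraries it was -0.91, with an exact permutation p of 0.0571, again the smallest possible.

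The second question was which other genes differed between tamoxifen and corn oil. At an FDR of 0.05 there were 5: Trp53, the p53 tumour suppressor, rose, and Creb3l4, Homer2, Tff1 and Fermt1 fell. Trp53 stood at 7.59 ± 1.47 normalised CPM (SD, n = 4) with corn oil and 149 ± 82.9 (SD, n = 6) with tamoxifen, a log2 fold change of 4.30 (SE 0.61, edgeR adjusted p 0.0362). Tamoxifen libraries ranged from 19.98 in replicate 4 to 225 in replicate 1. Tff1, a secreted trefoil peptide of gastric mucous cells, went from 5583 ± 3022 (SD, n = 4) to 241 ± 230 (SD, n = 6), a log2 fold change of -4.53 (SE 0.66, edgeR adjusted p 0.0362). Creb3l4, a membrane-bound transcription factor of the CREB3 family, changed by -3.88 (SE 0.50, edgeR adjusted p 0.0351) on the log2 scale. Homer2, a scaffold protein, changed by -3.26 (SE 0.44, edgeR adjusted p 0.0351). Fermt1, the epithelial kindlin that activates integrins, changed by -1.96 (SE 0.29, edgeR adjusted p 0.0362).

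**Figure D2:**
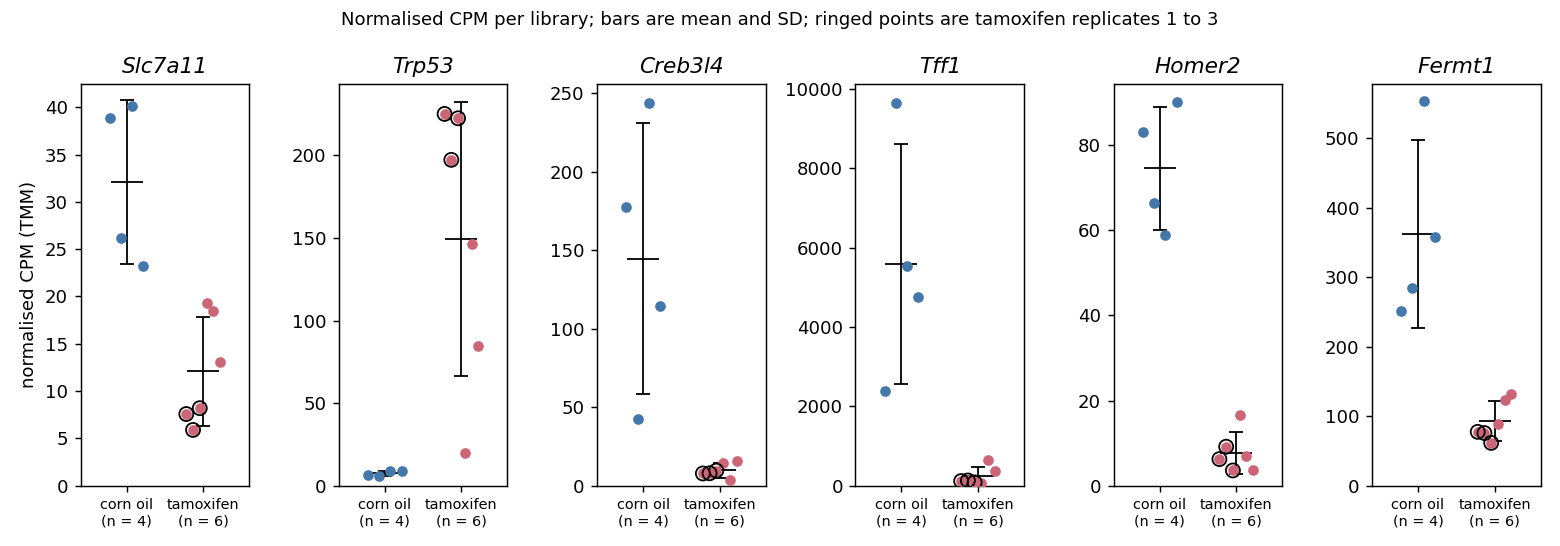
Normalised CPM (TMM-scaled, linear axes from 0) of Slc7a11 and of the 5 genes past an FDR of 0.05, with 1 point per library and bars for mean and SD. Corn oil (n = 4) and tamoxifen (n = 6) libraries do not overlap for any of the 6 genes, and ringed points are tamoxifen replicates 1 to 3.

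Trp53 lies on chromosome 11 at 69580359 to 69591873, Creb3l4 on chromosome 3 at 90237500 to 90243512, Homer2 on chromosome 7 at 81600481 to 81707527, Tff1 on chromosome 17 at 31161395 to 31165277 and Fermt1 on chromosome 2 at 132904389 to 132945906 of GRCm38. Homer2 and Tff1 each share exon sequence with 1 gene on the opposite strand, whose reads cannot be told apart without strand. Higher with tamoxifen but not past the FDR were Bhlhe40, Wrnip1, Slc4a4, Ndrg1, Gc, Nfil3 and Nudt9, with log2 fold changes of 1.09 to 3.28 and edgeR adjusted p of 0.0969 to 0.129. Lower but not past it were Pla2g10, Gsto1, Efna4 and Shisa2, with log2 fold changes of -7.91 to -1.43 and edgeR adjusted p of 0.0516 to 0.0858. At an unadjusted p under 0.05 there were 1262 of 13006 tested genes, 576 higher and 686 lower. Chance alone gives about 1 in 20 tested genes at that threshold. Groups did not overlap for 420 genes (3.23%), against 0.952% by chance if all 10 libraries are independent. With tamoxifen replicates 1 to 3 as 1 sample the chance is larger, since the smallest exact permutation p with 4 and 4 libraries is 0.0286. Whether 3.23% exceeds chance is therefore not settled.

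The 5 calls depend on single libraries. In edgeR the number of genes past an FDR of 0.05, tamoxifen against corn oil, was 0 without corn oil replicate 1 or 3. It was also 0 without tamoxifen replicate 1, 2 or 3. It was 1 without corn oil replicate 4, 2 without corn oil replicate 2, 9 without tamoxifen replicate 5 and 11 without tamoxifen replicate 4. These fits gave 894 to 1659 genes at an unadjusted p under 0.05. Without tamoxifen replicate 6 the number past the FDR stayed near 5. With sex as a covariate edgeR called 0 genes (1196 unadjusted). With tamoxifen replicates 1 to 3 counted as 1 sample edgeR also called 0 genes (709 unadjusted), and without them 0 (602 unadjusted). Chance alone puts about 1 in 20 tested genes under an unadjusted p of 0.05, so 709 and 602 show no clear excess. DESeq2 called 243 genes and limma voom with sample quality weights 1251 over all 10 libraries. Voom gave tamoxifen replicates 1 to 3 weights of 1.69, 5.49 and 3.87, against 0.308 and 0.333 for replicates 4 and 6, so its count leans on the 3 similar libraries.

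The third question was which gene groups moved. Markers of the classical pancreatic cancer subtype, an epithelial program with gastric and mucous genes, fell. Of 19 measured members 16 were lower, the median log2 fold change was -2.06, and 9 fell adjusted over the list alone against 1 (Tff1) over all genes. Camera gave an adjusted p of 1.44e-08, and this was the only list that held with an estimated correlation (adjusted p = 0.0204 with an estimated correlation). The exact permutation p of the list mean was 0.00952, adjusted to 0.133 over 28 lists. With tamoxifen replicates 1 to 3 counted as 1 sample the median was -1.74 and the adjusted p 0.0301 with an estimated correlation. Without these 3 the median was -1.50 and that adjusted p 0.0891, and without tamoxifen replicates 4 and 6 they were -2.16 and 0.0835, so the call was lost while the median stayed of similar size.

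Camera called 10 further lists with its preset correlation, none of which held with an estimated one. Hypoxia and glycolysis genes were higher as a set, with 24 of 25 members higher, a median of 1.21 and 13 risen adjusted over the list alone, 0 over all genes (adjusted p = 0.258 with an estimated correlation). The list's mean log2 CPM was 7.38 to 7.68 in 5 tamoxifen libraries, but 5.52 in tamoxifen replicate 4, within the 5.06 to 6.53 of corn oil. The median was 1.02 with tamoxifen replicates 1 to 3 counted as 1 sample and 0.80 without them. Its members Ndrg1 and Pfkfb3, a regulator of glycolysis, had log2 fold changes of 2.29 and 1.96. Mesenchymal transition genes had a median of 0.996 with 13 of 15 higher, Vim at 1.49 and Twist1 at 2.57 (adjusted p = 0.306 with an estimated correlation), and their median was 0.63 without corn oil replicate 2. Fibroblast markers moved with them, with a median of 0.73 and 15 of 19 higher (adjusted p = 0.449 with an estimated correlation), and Dcn was 18.1 ± 11.2 normalised CPM (SD, n = 4) with corn oil and 88.2 ± 106 (SD, n = 6) with tamoxifen. Tamoxifen replicate 4 stood at 291, and without it the log2 fold change of Dcn went from 2.28 to 1.39. The fibroblast list was no longer called without corn oil replicate 2 or tamoxifen replicate 4, with medians of 0.54 and 0.55, and had a median of 1.11 without corn oil replicate 4. Its median was 0.060 without tamoxifen replicates 4 and 6, where the call was lost, and 1.23 without replicates 1 to 3. Targets of p53 had a median of 0.32 with 15 of 20 higher (adjusted p = 0.302 with an estimated correlation), Mdm2 at 0.76 and Trp53inp1 at 1.77. Their mean log2 CPM was 4.53 to 4.92 in corn oil libraries and 4.98 to 5.45 in tamoxifen libraries. The exact permutation p of that mean was 0.00952, the smallest possible, adjusted to 0.133 over 28 lists. The p53 target list was no longer called without corn oil replicate 3, with a median of 0.46. It had medians of 0.50 and 0.51 without corn oil replicate 1 and tamoxifen replicate 6. Genes of the ATF4 amino acid response had a median of 0.47 with 26 of 38 higher and 1 risen adjusted over the list alone (adjusted p = 0.413 with an estimated correlation), with Ddit4 at 1.53 and Cars at 1.27. Immediate early and heat shock genes, which respond to tissue handling, had a median of 0.24 with 20 of 26 higher and 2 risen adjusted over the list alone (adjusted p = 0.413 with an estimated correlation), with Dusp1 at 1.44 and Klf6 at 1.25, and their median was 0.15 without corn oil replicate 2 and 0.49 without corn oil replicate 4.

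Cell cycle genes were lower as a set, with 31 of 37 members lower and a median of -1.40 (adjusted p = 0.413 with an estimated correlation). Ube2c had a log2 fold change of -1.85 and Pcna, the replication clamp, one of -0.82. Epithelial and ductal markers had a median of -0.63 with 19 of 23 lower and 2 fallen adjusted over the list alone (adjusted p = 0.446 with an estimated correlation), with Sox9 at -1.20 and Rab25 at -1.85. Cholesterol synthesis and uptake had a median of -0.60 with 19 of 21 lower and 1 fallen adjusted over the list alone (adjusted p = 0.474 with an estimated correlation), with Fdps at -1.46 and Hmgcs1 at -1.35. This list was no longer called without corn oil replicate 2 or 4, with medians of -0.29 and -0.35, and without corn oil replicate 4 Fdps was at -0.86. Without corn oil replicate 3 or tamoxifen replicate 4 its median was -0.94 and -1.08. Nuclear-encoded respiratory chain subunits had a median of -0.36 with 32 of 40 lower (adjusted p = 0.431 with an estimated correlation), with Cox5b at -0.95 and Atp5a1 at 0.66. Without tamoxifen replicates 1 to 3 camera no longer called the epithelial, cholesterol, respiratory chain and ATF4 lists, whose medians were then -0.13, -0.19, -0.21 and 0.25. With these 3 counted as 1 sample it no longer called the epithelial list, at a median of -0.37.

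**Figure D3:**
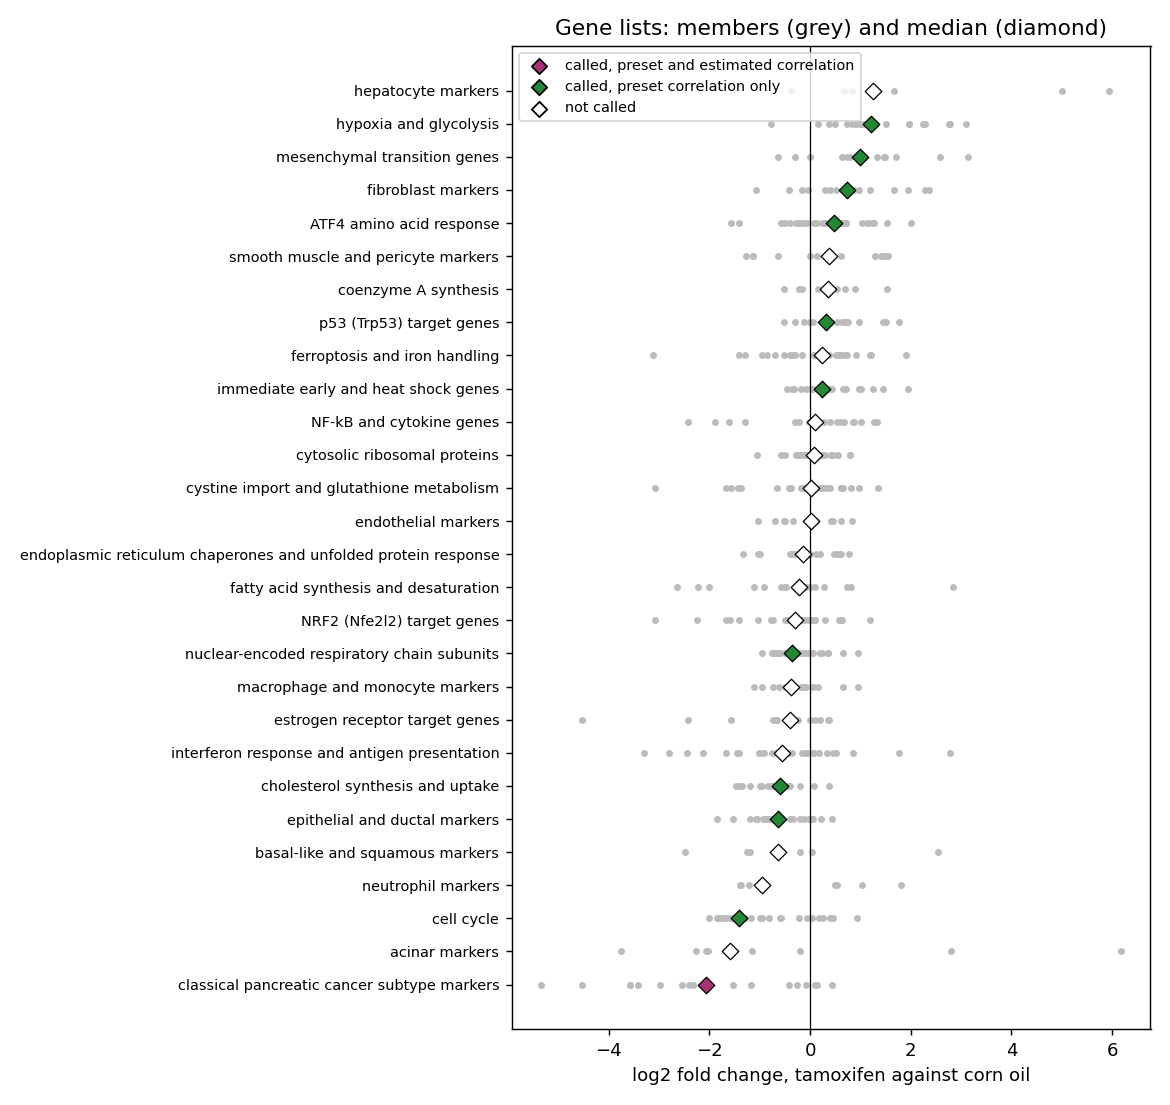
Log2 fold change of tamoxifen against corn oil for the members (grey points) and median (diamond) of the 28 tested gene lists. Purple marks the classical subtype list, called with a preset and an estimated correlation, green the 10 called with the preset correlation only and white those not called.

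Lists tied to cystine and redox metabolism were not called. NRF2 targets, antioxidant genes, had a median of -0.30 with 21 of 29 lower and 2 fallen adjusted over the list alone (camera adjusted p 0.0516), with Cbr3 at -1.68 and Gpx2 at -3.08. That list was called in 10 of 24 alternatives, among them without corn oil replicate 3 or 4 or without tamoxifen replicate 5 or 6, with medians of -0.22, -0.29, -0.27 and -0.39, and the adjusted p ran from 0.00578 to 0.858. Its median was -0.14 without corn oil replicate 1, -0.075 with tamoxifen replicates 1 to 3 counted as 1 sample and -0.0076 without them. Cystine import and glutathione metabolism had a median of 0.02 over 27 members and 2 fallen adjusted over the list alone (camera adjusted p 0.230), and its camera direction was down although its median was above 0. That median ran from -0.16 (without corn oil replicate 3) to 0.086 (without corn oil replicate 2) with 1 library left out, and was -0.31 without tamoxifen replicates 4 and 6, so its sign is not settled. Ferroptosis and iron handling had a median of 0.25 over 32 members (camera adjusted p 0.461), with Trf at 1.90. Its median was -0.062 without tamoxifen replicate 6 and -0.19 without tamoxifen replicates 4 and 6. Coenzyme A synthesis had a median of 0.36 over 10 members (camera adjusted p 0.264). The camera adjusted p was 0.118 for estrogen receptor targets, 0.154 for basal-like markers, 0.154 for ribosomal proteins, 0.287 for NF-kB and cytokine genes, 0.346 for endoplasmic reticulum chaperones, 0.408 for fatty acid synthesis and 0.861 for interferon response genes, where camera pointed up although the median was -0.56. Tff1 was the member of the estrogen receptor list that fell over all genes and over the list alone, and 1 chaperone gene had fallen adjusted over the list alone, 0 over all genes. NF-kB genes had a median of 0.09 and a mean just below 0. Their median was 0.30 with tamoxifen replicates 1 to 3 counted as 1 sample, 0.49 without them and -0.04 without replicates 4 and 6. Of other cell types the camera adjusted p was 0.124 for acinar, 0.187 for hepatocyte, 0.242 for macrophage, 0.676 for neutrophil, 0.766 for endothelial and 0.963 for smooth muscle and pericyte markers. Of their members 1 macrophage gene had risen adjusted over the list alone, 0 over all genes, and the endothelial median was 0.01 while camera pointed down. Of 17 macrophage markers 13 were lower, with a median of -0.37. That median was 0.037 with tamoxifen replicates 1 to 3 counted as 1 sample, 0.29 without them and -1.35 without replicates 4 and 6. Its sign is therefore not settled. The most abundant macrophage markers, Cd14 and Lyz2, were at 0.95 and -0.42, and Mrc1 at -1.12, and Lyz2 was at 0.19 without tamoxifen replicates 1 to 3. Lymphocyte, erythroid, endocrine islet and adipocyte markers and sex-linked genes had fewer than 5 tested members and were not tested.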

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

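The tests of gene order, of depth and of other splits of the samples were chosen before their results were seen. The tests of repeated deposit, of the region around Trp53, of stromal RNA, of the NRF2 and ATF4 lists and of Trp53 and Slc7a11 without tamoxifen replicates 1 to 3 were chosen after.

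In 18 of 223 comparisons of 1 library with the rest of its group a library stood apart, where chance gives about 1 in 20. Tamoxifen replicate 4 was lowest for Ndrg1 (69.7 normalised CPM, others 229 to 425), for Cidec (4.21, others 17.7 to 22.2) and for the mean log2 CPM of the hypoxia list (5.52, others 7.38 to 7.68). Tamoxifen replicate 6, the shallowest library, was lowest for Shisa2 (0.163, others 2.26 to 8.63), Coasy (18.5, others 53.9 to 65.8), Elovl6 (0, others 3.77 to 12.1) and the mean log2 CPM of the fatty acid list (3.16, others 4.19 to 4.75). It was highest for Klf6 (2015, others 789 to 1106), Mmp8 (34.5, others 0.853 to 3.31) and Fbln2 (1390, others 461 to 694). Tamoxifen replicate 5 was highest for the mean log2 CPM of estrogen receptor targets (4.84, others 3.38 to 3.72). Corn oil replicate 1 was highest for the mean log2 CPM of interferon genes (5.33, others 1.45 to 2.02) and for Fga (0.554, others 0). Corn oil replicate 2 was lowest for Lum (0.579, others 5.28 to 6.10). Corn oil replicate 3 was lowest for Cidec (1.65, others 25.8 to 38.2) and highest for Alb (0.363, others 0). Corn oil replicate 4 was lowest for Cbr3 (51.2, others 191 to 223) and highest for Rpl3 (575, others 398 to 415).

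Tamoxifen replicates 1 to 3 were closer to each other than any other libraries. A library deposited more than once would differ by counting noise alone, and the smallest mean chi-square per gene, 25.04, is far above the value near 1 this needs. Windows of 50 neighbouring genes were scaled by the standard error of a 50-gene mean, with genes taken as independent. Of 235 windows, 14 were shifted the same way by over 2 standard errors in all 3 libraries. The highest count was 6 in 1000 shuffles of gene order and 3 in the 119 other triples of libraries. All 3 libraries were male by Xist and Ddx3y. These shared windows could come from pieces of 1 tumour with shared chromosomal changes, and neighbouring genes that are regulated together in similar tumours may give such windows too. The 3 were picked as the most alike libraries, so exceeding other triples adds little. Of the 6 tamoxifen libraries 5 were male, so a shared sex adds little too. Windows beyond 4 of these standard errors numbered 1, 2 and 3 in these libraries, 0 to 1 in the other tamoxifen libraries and 4 to 8 with corn oil. The labels do not settle whether the 3 share a tumour.

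Trp53 was higher in each tamoxifen library than in any corn oil library. A gain of the region is argued against by the 66 other tested genes within 1 Mb, whose median log2 fold change was 0.0028, with a highest value of 1.52. Stromal cells with an intact allele are argued against because the highest median of the fibroblast, endothelial, smooth muscle and macrophage lists was 0.73, far below the 4.30 of Trp53, with Lum, Dcn and Tagln at 2.36, 2.28 and 1.55 and the abundant Fbln2 and Tpm2 at 0.69 and 0.0012. Without tamoxifen replicates 1 to 3 the log2 fold change was 3.46 (SE 0.61), so these do not carry it alone. An allele of Trp53 that depends on the recombinase may be involved, which was not tested, since reads per exon were not analysed here.

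Slc7a11 was lower in each tamoxifen library. The other NRF2 targets had a median of -0.24 (95% bootstrap interval over genes -0.43 to -0.01) and the other ATF4 genes one of 0.48 (0.13 to 0.64), which argues against a general fall of either group as the whole cause. These intervals treat genes as independent and leave out the spread between libraries. Some NRF2 targets fell more than Slc7a11, such as Gpx2 at -3.08 and Cbr3 at -1.68, while 8 of 29 were higher. A fall of part of that group stays open. After thinning to the smallest total of 6899350 counts the log2 fold change of Slc7a11 was -1.32 without overlap, so the difference remained at equal counts. Thinning hardly moves the expected CPM of a gene with at least 80 reads per library, so little change could arise. Other differences between low-input libraries were not tested. Without tamoxifen replicates 1 to 3 the log2 fold change of Slc7a11 was -0.91 (SE 0.49), too imprecise to tell whether these libraries carry most of it. Deletion by tamoxifen, the contrast of the design, stays open, as reads per exon were not analysed here.

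Of 100 splits of the 10 libraries into 4 and 6, drawn from 210, 2 gave at least 5 genes past the FDR, the real one included, and the highest other split gave 5. That share is under 0.05, but it treats tamoxifen replicates 1 to 3 as independent samples. Of the 25 splits that keep these 3 on one side 2 gave at least 5 genes, the real one and that of tamoxifen replicates 1, 2, 3 and 5 against the rest, and of the 75 that part them 0 did. Chance is therefore not excluded for that count if these 3 share an origin. Counted as 1 sample they left 0 genes in edgeR, with 709 at an unadjusted p under 0.05, where chance gives about 1 in 20 tested genes. Over all 10 libraries DESeq2 called 243 genes and limma voom 1251. For gene lists 15 of 100 splits gave at least 11, the real one included, with 13 as the highest and 8 as the median of the others. Chance is therefore not excluded for the number of lists camera called with its preset correlation.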

How the results depend on the processing

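The alternatives that set tamoxifen replicates 1 to 3 or 4 and 6 apart and the count at equal depth were chosen after seeing the data. The main count of 5 genes past an FDR of 0.05, tamoxifen against corn oil, became 1251 with limma voom, 243 with DESeq2, 16 with detected genes as a covariate, 8 with the fibroblast level, 18 at an FDR of 0.1 and 0 in edgeR with sex as a covariate (1196 at an unadjusted p under 0.05). It became 0 with tamoxifen replicates 1 to 3 counted as 1 sample (709 unadjusted) or left out (602 unadjusted), with fewer samples, and 77 without tamoxifen replicates 4 and 6. The 709 and 602 show no clear excess over the 1 in 20 tested genes that chance gives. Leaving out 1 library gave 0 to 11 genes. The other causes were not tested. Slc7a11 kept its direction in every alternative, at -1.59 to -1.24 with 1 library left out, with adjusted p of 0.00405 (voom) to 0.980, and lost its unadjusted threshold without tamoxifen replicates 1 to 3 (-0.91). The 11 lists became 1 with an estimated correlation, 1 with fry and 0 with exact permutation, and 11 to 16 with 1 library left out. Of 24 alternatives, the call was lost in 8 for fibroblast markers, in 6 each for cholesterol, immediate early and heat shock and p53 target genes, in 5 for epithelial markers, in 4 each for mesenchymal, respiratory chain and ATF4 genes, in 3 each for hypoxia and cell cycle genes and in 1 for the classical list. Most of these alternatives kept the preset correlation of 0.01, so few losses do not show that a call is robust. The losses of the hypoxia and cell cycle lists were those with an estimated correlation, fry and exact permutation. With an estimated correlation the classical list was also lost without tamoxifen replicates 1 to 3 and without 4 and 6. The NRF2 list was called in 10. The fibroblast median was lowest with voom, at -0.19.

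Leaving out 1 library, the group difference ran from -13718800 to -7165970 in total count, from -472.2 to 134 in genes with a count (higher with tamoxifen without replicate 6) and from -3.33 to -2.34 percentage points in the share of the 10 most abundant genes. An exact permutation p under 0.05 was lost for the total count in all but the fit without corn oil replicate 1, and for that share in all but the fit without tamoxifen replicate 6.

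All 16 genes named for the FDR or the smallest p kept their direction in every alternative, as did 49 of 63 other named genes. The 16 were chosen by p in these same data, so their kept direction is no independent support. The 14 that turned were called neither in the main test nor where they turned. With voom the log2 fold change was -0.18 for Ly6d, -0.66 for Mmp8, -1.998 for Ly6c1, -0.052 for Col3a1, -0.013 for Tpm2, -0.41 for Acta2, -0.798 for Lck, -2.33 for Reg1 and 0.42 for Cidec. With the fibroblast level it was -0.24 for Ly6c1, -0.042 for Col3a1, -0.093 for Tpm2, 0.81 for S100a8, -0.057 for Lck, -1.67 for Reg1 and -0.21 for Apoa1. With sex it was 0.76 for Flt1 and -0.48 for Apoa1, with detected genes -0.031 for Mmp8, and for Tpm2 -0.0071 with upper-quartile factors and -0.011 with the stricter filter. Without tamoxifen replicates 1 to 3 it was 0.19 for Lyz2 and -0.42 for Ttr, and without 4 and 6 it was -0.42 for Mmp8, -0.17 for Acta2 and -0.99 for Lck. With 1 library left out the range was -0.24 to 2.92 for Ly6d, -0.23 to 2.06 for Mmp8, -0.84 to 1.10 for Flt1, -0.14 to 0.23 for Tpm2, -0.061 to 0.89 for Acta2 and -2.22 to 0.50 for S100a8. The ferroptosis list, with a median of 0.25, had a mean in the other direction in the exact permutation. Scaling moved the median of all genes by at most 0.014. Tamoxifen replicate 6 was the shallowest library, but depth does not account for all of its difference. Counted at equal depth it still held the fewest genes, 11643 against 12337 to 14288 in the other libraries. On the first principal component of log2 CPM, with 29.9% of variance, it stood at 233, and the other libraries at -47.3 to 45.7. In simulated data the test recovered 4% of 2-fold changes.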

Other observations

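The lists for glucocorticoid-responsive and mucous secretory genes and their predictions were written after the genes that prompted them were seen and before any values of the tested members were seen, except that Lcn2 also belongs to a list fixed earlier. Gkn3, Spdef, Fkbp5 and the members named here were chosen after their values were seen. Both lists were tested in the same 10 libraries as the genes that prompted them. Genes regulated together would move with the prompting genes, so neither test is independent and its exact p does not allow for this choice.

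Gastric mucous genes beyond the classical list were low with tamoxifen. Gkn3, a gastrokine, stood at 6297 ± 2930 normalised CPM (SD, n = 4) with corn oil and 87.2 ± 114 (SD, n = 6) with tamoxifen (edgeR adjusted p 0.0969), and Spdef, a transcription factor of mucous cells, at 95.8 ± 41.1 and 3.74 ± 3.82 (edgeR adjusted p 0.113). The hypothesis that a wider mucous secretory program is lost was tested on other genes of it. All 17 tested members of the 20 listed were lower, with a median log2 fold change of -1.72, and the exact permutation p of the list mean was 0.009524, the smallest possible, adjusted to 0.0190 over the 2 hypotheses. No member passed the FDR over all genes. Ern2 and Gkn2 had log2 fold changes of -4.10 and -5.32. The difference of list means was -2.56 in log2 CPM, -2.10 with tamoxifen replicates 1 to 3 counted as 1 sample (exact p 0.0286) and -1.63 without them (exact p 0.0571), each p the smallest possible, so these 3 libraries add to its size. The result is consistent with a wider loss, though this list and the classical list describe much the same cells and are not independent.

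Fkbp5, a glucocorticoid-induced chaperone, stood at 47.9 ± 25.1 normalised CPM (SD, n = 4) with corn oil and 237 ± 79.3 (SD, n = 6) with tamoxifen (edgeR adjusted p 0.129). The hypothesis of a higher glucocorticoid response was tested on other responsive genes. Of 19 tested members 16 were higher, with a median log2 fold change of 0.89, and the exact permutation p of the list mean was 0.0381, with an adjusted p of 0.0381 and the same p without Lcn2. The difference of list means was 1.16 in log2 CPM, 1.05 with tamoxifen replicates 1 to 3 counted as 1 sample (exact p 0.114) and 0.95 without them (exact p 0.229, where 4 and 3 libraries can give no p below 0.0571). The size changed little, and these smaller comparisons do not settle whether the difference exceeds the spread between samples. Immediate early and heat shock genes, which respond to tissue handling, were higher too in 20 of 26 members. The camera adjusted p was 0.00267 with the preset correlation and 0.413 with an estimated one, so that rise is not settled. Dusp1 at 1.44, which helped prompt the hypothesis, belongs to that list, so handling stays open. Tsc22d3 had a log2 fold change of 1.94 and Zbtb16 one of 3.90, and no member passed the FDR.

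Ins2, insulin, was read 2256 times in corn oil replicate 1, 36 to 171 times in the other corn oil libraries and 0 times in each tamoxifen library.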
